A study of Mus musculus with 14 samples.

How the data were processed

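RNA from 14 samples of C57BL/6 mouse material was measured on an Affymetrix gene array, with 1 array per sample and 2 arrays in each of 7 groups. The organoid groups were gallbladder, differentiated gallbladder, liver and small intestine organoids, and the tissue groups were gallbladder, liver and small intestine. Per the labels, differentiated gallbladder organoids were kept for 2 weeks in medium without R-spondin 1, noggin and nicotinamide. The deposited values are log2 probe set signals made by the authors with RMA (robust multi-array average); its version was not given. No raw signal or detection call was used, so the noise floor of each array is unknown, and the number of arrays limits the precision.

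The table held 35556 probe sets. The array annotation gave 1 gene symbol to 21789 of them, several to 1621, and left 12146 unlisted. Of the probe sets with 1 symbol, 21698 were matched by gene number to a mouse reference table, which changed 0 symbols. Probe sets with several symbols or none were left out. For the 999 genes with more than 1 probe set, the probe set with the highest mean signal was kept, which left 19938 genes, all of them tested.

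Groups were taken from the sample titles. A linear model with 1 mean per group was fitted to all 14 arrays with limma 3.58.1 in R 4.3.3 (7 residual degrees of freedom, 9.91 with those from the prior, no intensity trend). Each comparison was tested with limma's moderated statistic, 2-sided, and adjusted by Benjamini-Hochberg over the 19938 genes. A gene was called at an adjusted p below 0.05. The 10 comparisons set organoids against each other, organoids against tissue, and tissues against each other. Differences between organoid-tissue changes were tested as interaction terms of the same model. An exact permutation test of 2 arrays against 2 cannot give a 2-sided p below 0.333. Regroupings of the samples need groups of at least 3, so none were run.

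A tissue signature held the genes higher in 1 tissue than in each of the other tissues by at least 2 log2 units and called in both comparisons, from a fit to the 6 tissue arrays alone. A separate fit to the 6 arrays of undifferentiated organoids gave the genes higher in the organoids of 1 origin than in those of both others. The share of signature genes among them was set against the share among all genes with Fisher's exact test, 2-sided.

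There were 28 gene lists. They covered Wnt target genes, intestinal stem cell genes, epithelial progenitor markers, BMP target genes, Notch pathway genes, cell cycle genes, bile duct epithelium markers, gallbladder epithelium markers and transporters, bile acid synthesis and transport, hepatocyte markers, enterocyte markers, intestinal secretory cell markers, tuft cell markers, gastric and mucin genes, squamous and basal keratinocyte genes, YAP target and fetal-like epithelium genes, cholesterol synthesis genes, hypoxia and glycolysis genes, nicotinamide and NAD genes, interferon response genes, and immediate early and stress genes. The remaining lists were markers of smooth muscle, fibroblasts, endothelium, immune cells, neural and glial cells, pancreatic acinar cells and adipocytes. Each list was tested in each comparison with camera from limma at a preset correlation of 0.01, adjusted over 280 tests. The tests were repeated with a correlation estimated from the data and with fry, which asks whether the genes of a list move 1 way and compares them with no other genes.

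Named genes followed a rule. In each of the 4 comparisons of gallbladder organoids with another group these are the 8 called genes with the largest difference in each direction whose arrays do not overlap, and in the other comparisons the top 4. To these come 14 genes named in every comparison and the 4 members of a list with the largest differences. Genes outside the rule that are named were chosen after their values were seen.

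The groups, comparisons, lists, naming rule and first set of alternatives were fixed before the data were examined. The alternatives were quantile normalisation, centring each array on its median, leaving out the dimmest 40% of genes, averaging the probe sets of a gene, fitting only the arrays of the groups compared, array weights, a variance prior with an intensity trend and robust fitting, a minimum difference of 1 log2 unit, other minimum differences for the signatures, the replicate number as a block, and leaving out each array in turn. Alternatives chosen after seeing the data left out genes higher in liver tissue, left out pancreatic acinar markers, chose the gallbladder signature without gallbladder tissue replicate 2, or crossed the replicate numbers in the block.

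The code was tested on simulated data. Of 50 planted genes at each of 0.5, 1, 2 and 3 log2 units, 11, 38, 49 and 50 were called in a comparison of 2 against 2 arrays, with 10 false calls among 158. Of 28 simulated lists with no shift, 1 had an unadjusted p below 0.05 and 0 were called. The simulated genes varied independently and with the same SD in every group. These tests therefore check the code and do not give the error rates of the real arrays, where genes of a list can move together.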

Results

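Gene expression was measured on 14 arrays, 2 for each of 7 groups of mouse material. Organoids, which are epithelial cultures grown in a gel from primary tissue, came from small intestine, from liver and from gallbladder. A further set of gallbladder organoids, called differentiated, had spent 2 weeks without R-spondin 1, noggin and nicotinamide, and the tissues of the same 3 organs completed the set. R-spondin 1 strengthens Wnt signalling and noggin blocks BMP signalling. Array medians lay between 7.12 and 7.44 on the log2 scale, and the small number of arrays limits the precision. Replicates correlated across genes at r = 0.998 in gallbladder organoids and in differentiated organoids, 0.997 in small intestine organoids and 0.996 in liver organoids. In tissue this was 0.983 for liver, 0.972 for small intestine and 0.965 for gallbladder, where genes are not independent replicates. The pooled SD of a gene between replicates was 0.0952 to 0.136 log2 units in the organoid groups and 0.289 to 0.404 in the tissues. Nothing in the labels says that replicates came from separate animals or cultures, so the p-values may measure technical spread. Gallbladder tissue replicates 1 and 2 differed in Xist (13.51 and 5.46) and the Y-linked Eif2s3y (3.72 and 10.0), which argues against a shared animal for that group alone. Signals of 14 or more, a level chosen after seeing the data, lie near the top of the scale and compress differences. The differences given for Alb, Ahsg, Serpina1c, Cyp2e1, Car3, Acta2 and Dmbt1 against gallbladder tissue or between tissues, for Alb, Fgg, Pon1 and Serpina1c against liver tissue, for Zg16 and Pmp22 against small intestine tissue, and for Lcn2 and Lyz1 between organoids involve such signals. Where only 1 of the groups is near the top, the size is likely understated and the rank is not exact. Alb is near the top in both gallbladder and liver tissue, so its difference between them bounds nothing. All differences are on the log2 scale, with n = 2 arrays per group, and adjusted p-values come from limma.

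The comparison of differentiated with undifferentiated gallbladder organoids asks what changes when the 3 factors are withdrawn. Markers of tuft cells, the chemosensory cells of epithelia, rose after withdrawal: Rgs13 (probe set 10358399) by 5.69 ± 0.35 (SE, adjusted p = 2.16e-05), from a mean of 4.92 to 10.62, and Gnat3, the gustatory G protein, by 4.53 ± 0.29 (adjusted p = 2.95e-05). Lgr5 (probe set 10372503), the receptor for R-spondins and a stem cell marker, fell by 3.15 ± 0.40 (adjusted p = 0.00142), from 10.37 to 7.23. Axin2, a general Wnt target, fell by 0.62 ± 0.10 (adjusted p = 0.00754). In all, 559 genes were higher and 384 lower in differentiated organoids, and the median difference over all genes was -0.04.

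The genes that rose most after Rgs13 were Cyp2c65, a cytochrome P450 (5.22 ± 0.38), Rasgrp3, an activator of Ras proteins (4.89), Cyp2f2 (4.56), Gnat3, the sulfotransferase Sult1d1 (4.45), the trefoil factor Tff2 (4.24) and the placental hormone family member Prl2c5 (4.01). Those that fell most were Trf, which encodes the iron carrier transferrin (-4.40 ± 0.23, adjusted p = 7.43e-06), Chil1, a chitinase-like protein (-3.67), Cyp1b1 (-3.45), Armcx2 (-3.31), the antimicrobial lectin Reg3b (-3.29), Lgr5, Slfn2 (-2.91) and Heg1 (-2.83). Tff2 had an adjusted p of 0.0281, and of 0.168, 0.174, 0.183 and 0.156 without differentiated organoid replicates 1 and 2 and gallbladder organoid replicates 1 and 2. Reg3b had one of 0.0415, and without the same 4 arrays 0.215, 0.227, 0.227 and 0.209. Its call also ended without either small intestine organoid array (0.0694 each), either liver tissue array (0.0557 each) or either liver organoid array (0.071 each). Axin2 was not called without differentiated organoid replicate 2 (0.0954) or gallbladder organoid replicate 1 (0.0981).

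Among the tuft cell markers, 8 of 12 rose (8 adjusted over the list alone), with Dclk1 at 2.22 and the ion channel Trpm5 at 2.14. The list shifted up by camera (adjusted p = 2.09e-12), with an adjusted p = 0.121 with an estimated correlation. Without differentiated organoid replicate 1 or gallbladder organoid replicate 1, 5 of its members rose. Undifferentiated gallbladder organoids were also below other organoids in some of these genes. Rgs13 read 9.95 and 9.40 in liver organoids and 10.42 and 9.43 in small intestine organoids. Trpm5 read 8.59 and 8.26 in liver organoids and 9.14 and 8.25 in small intestine organoids. Gnat3 was high in liver organoids (9.03 and 8.43) but low in small intestine organoids (4.56 and 4.46). Of 15 intestinal stem cell genes 3 fell (4 adjusted over the list alone, and 1 rose), and the list shifted down at adjusted p = 0.0442, with an adjusted p = 0.204 with an estimated correlation. That call ended without gallbladder organoid replicate 1 (0.0702), small intestine tissue replicates 1 (0.0771) and 2 (0.0805), and liver organoid replicates 1 (0.0683) and 2 (0.0702). Of 16 Wnt target genes 2 fell, Lgr5 and Axin2 (2 adjusted over the list alone), and the list itself did not pass (adjusted p = 0.119). Without differentiated organoid replicate 2 or gallbladder organoid replicate 1, 1 member of the stem cell list and 1 of the Wnt list fell.

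Markers of bile duct epithelium shifted up (adjusted p = 0.0152), with an adjusted p = 0.339 with an estimated correlation, and 4 of 15 rose (4 higher and 1 lower adjusted over the list alone). They included the water channel Aqp1 (2.13), the Notch ligand Jag1 (0.85) and Pkhd1 (1.23), the gene of autosomal recessive polycystic kidney disease. Without differentiated organoid replicate 1 or 2, 1 of these markers rose, without gallbladder organoid replicate 1 it was 2, and without replicate 2 it was 0. Aqp1 had adjusted p-values of 0.0518, 0.0712, 0.054 and 0.0656 without each of these 4 arrays in that order, Jag1 had 0.0959, 0.067 and 0.103 without the differentiated replicates and gallbladder organoid replicate 2, and Pkhd1 had 0.0553 without the last. Hypoxia and glycolysis genes shifted down (adjusted p = 0.0039), with an adjusted p = 0.522 with an estimated correlation. Of these 15 genes 2 fell (3 adjusted over the list alone), Bnip3 (-2.60) and P4ha1 (-1.59). Bnip3 was not called without differentiated organoid replicate 1 (0.102) or gallbladder organoid replicate 1 (0.1), nor P4ha1 without those (0.0649 and 0.0777) or differentiated organoid replicate 2 (0.0596). The number of members that fell was 0 without the first pair, 1 without differentiated organoid replicate 2, and 4 without either liver tissue array.

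Cell cycle genes shifted up as a list (median 0.14, adjusted p = 0.0081), with an adjusted p = 0.607 with an estimated correlation, and an adjusted p = 0.0812 without gallbladder organoid replicate 1. limma called 0 of its 43 members (0 adjusted over the list alone), and at an unadjusted p under 0.05 there were 6 higher and 1 lower. The proliferation marker Mki67 was at 0.64 (adjusted p = 0.165). Further genes of progenitor cells and of the biliary lineage did not pass: Sox9 -0.71 (adjusted p = 0.117), Prom1 -0.37, Cd44 -0.25, Lgr4 0.30, Krt19 0.29, Epcam -0.22, Sox17 0.18, Pdx1 -0.25, Gata4 0.02, Cdx2 -0.67 and Alb 0.12. As the common variance includes the more variable tissue arrays, a gene that did not pass may still differ.

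The other lists did not pass camera, and single members changed in some. Aldh1a1, an enzyme of retinoic acid synthesis, rose by 2.62 among 14 epithelial progenitor markers, of which 1 rose and 2 fell (1 and 3 adjusted over the list alone). Of 13 Notch pathway genes 1 rose and 1 fell (1 and 1 adjusted over the list alone), the latter being the Notch target Hey1 (-1.86). Transthyretin (Ttr) rose by 2.20 among 30 hepatocyte markers, of which 2 rose and 1 fell (2 and 1 adjusted over the list alone). Goblet cell genes Tff3 (3.28) and Clca1 (1.82) were among 3 of 21 intestinal secretory cell markers that rose (3 adjusted over the list alone). Anxa10, a gastric gene, rose by 3.89 among 14 gastric and mucin genes (3 rose and 1 fell, and 5 and 1 adjusted over the list alone). Of 14 squamous and basal keratinocyte genes 2 rose, Dsg3 (2.50) and Krt4 (2.17), against 2 higher and 1 lower adjusted over the list alone. Gallbladder epithelium markers gave 2 higher of 20 (2 adjusted over the list alone), neural and glial markers 1 of 8, S100b at 1.03 (1 adjusted over the list alone), and enterocyte markers 1 lower of 23 (2 higher and 2 lower adjusted over the list alone).

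These small counts changed when an array was left out, also one of a group not compared, so they do not point at any 1 array. Leaving out an array also removes replication and changes the variance estimate. Leaving out any 1 of the 4 arrays compared gave 1 progenitor marker lower, 1 hepatocyte marker higher, 0 gallbladder epithelium markers, 1 gastric gene higher and 0 lower, and 0 enterocyte markers lower. Without either small intestine organoid array the progenitor, hepatocyte, lower gastric and enterocyte counts were the same 1, 1, 0 and 0, and without either liver organoid array the progenitor, lower gastric and enterocyte counts were 1, 0 and 0, with 1 enterocyte marker higher. The Notch member that rose was not called without differentiated organoid replicate 1 or 2 or gallbladder organoid replicate 2. Without either gallbladder tissue array there were 5 gastric genes higher, 2 enterocyte markers higher and 2 lower, 2 hepatocyte markers lower and 2 neural and glial markers higher.

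In 13 more lists limma called 0 members of the differentiated comparison. At an unadjusted p under 0.05, BMP targets, cholesterol synthesis, nicotinamide and NAD genes, immediate early genes and markers of smooth muscle, fibroblasts, acinar cells and adipocytes also gave 0, as they did adjusted over the list alone. Bile acid genes gave 2 higher (1 adjusted over the list alone) and interferon response genes 1 higher and 3 lower (1 and 3 adjusted over the list alone). YAP targets gave 2 higher, endothelial markers 1 lower, and immune cell markers 4 higher and 1 lower, with 0 of these adjusted over the list alone. The median, the mean and the camera direction differed in sign for 9 lists of this comparison, 0 of them called. The number of called genes, 943, was 338 without gallbladder organoid replicate 1, 372 without its replicate 2, and 343 and 344 without differentiated organoid replicates 1 and 2. It was 5353 when only these 4 arrays were fitted, which leaves out the spread of the more variable tissue arrays, and 5720 with array weights (48.2% higher against 59.3%). With the replicate number as a block it was 888, of which 852 were among the 943.

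**Figure D1:**
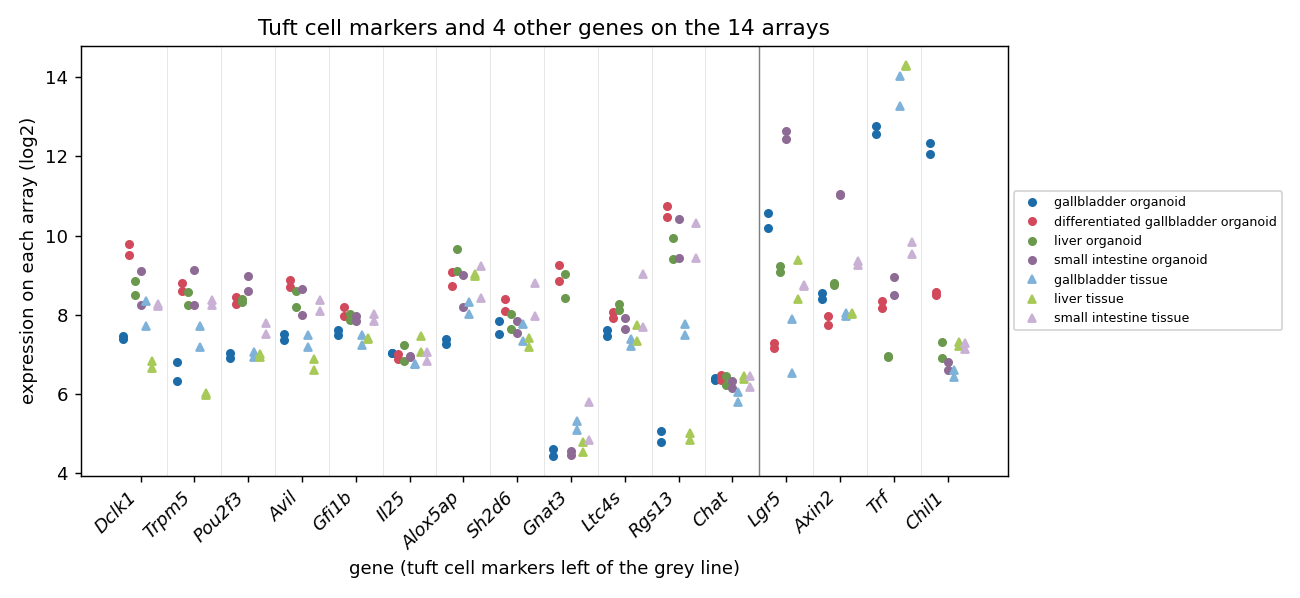
Log2 signal of 12 tuft cell markers and of Lgr5, Axin2, Trf and Chil1 on each of the 14 arrays, by group (circles are organoids, triangles are tissues, each point is 1 array). Rgs13 averaged 4.92 in gallbladder organoids and 10.62 after 2 weeks without the factors, and Lgr5 averaged 10.37 and 7.23.

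Gallbladder and liver organoids were compared to see what sets apart cultures from these neighbouring parts of the biliary tree. Transferrin (Trf, 5.70 ± 0.23, adjusted p = 9.48e-07), Chil1 (5.09), the sialyltransferase St8sia6 (3.97), Heg1 (3.62), Armcx2 (3.38) and the GLP-1 receptor Glp1r (3.06) were higher in gallbladder organoids. So was Reg3b, at -4.02 when taken as liver minus gallbladder organoids. Lower were Sult1d1 (-5.95 ± 0.47, adjusted p = 4.86e-05), Cyp2f2 (-5.46), Rgs13 (-4.75), Gnat3 (-4.20), the fatty acid binding protein Fabp7 (-4.19), Prap1 (-4.05), Dnase1l2 (-3.96) and the retinol binding protein Rbp2 (-3.94). In total 1231 genes were higher and 1299 lower.

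Tuft cell markers were lower in gallbladder organoids, with 7 of 12 members (8 adjusted over the list alone) including Alox5ap (-2.05) and Trpm5 (-1.85), and adjusted p = 1.42e-07, against an adjusted p = 0.224 with an estimated correlation. BMP target genes were lower as well (adjusted p = 0.000995), with an adjusted p = 0.0751 with an estimated correlation. The 4 members called of 11 (4 adjusted over the list alone) included the transcriptional regulators Id3 (-2.45) and Atoh8 (-2.06), and leaving out any 1 of the 4 arrays compared left 2. Cell cycle genes were higher (adjusted p = 2.03e-05), with an adjusted p = 0.342 with an estimated correlation. There were 12 higher and 1 lower among 43 (19 and 1 adjusted over the list alone), among them cyclin E (Ccne1, 1.30) and E2f1 (0.81). The number higher was 6 and 4 without gallbladder organoid replicates 1 and 2, and 5 and 4 without liver organoid replicates 1 and 2, and the gene that was lower was not called without any of these 4 arrays or any array of the differentiated or small intestine organoids.

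Hypoxia and glycolysis genes were lower in gallbladder than in liver organoids (adjusted p = 0.00489), with an adjusted p = 0.545 with an estimated correlation, and 2 of 15 were called (3 adjusted over the list alone), among them the kinase Pdk1 (-1.11). Without gallbladder organoid replicate 1 or 2 or liver organoid replicate 2 this was 1, and without any liver or gallbladder tissue array it was 4. Interferon response genes shifted down (median -0.54, adjusted p = 0.0158), with an adjusted p = 0.73 with an estimated correlation and 0.125 without liver organoid replicate 2. Markers of organ and region did not pass between these organoids: Sox17, a regulator of biliary and gallbladder fate, was at -0.46 (adjusted p = 0.14), Krt19 at -0.37 (0.0699), Pdx1 at -0.51 (0.709), Alb at 0.27 (0.765), Cdx2 at 0.28 (0.504) and Lgr5 at 1.21 (0.0775). The common variance includes the more variable tissue arrays, so calls between organoids can be too few. Krt19, for one, read 13.35 and 13.43 in gallbladder and 13.76 and 13.77 in liver organoids. The chloride channel Cftr (1.26) and the sodium-proton exchanger Slc9a3 (3.01) were higher in gallbladder organoids, and Pkhd1 (-1.88), Jag2 (-1.35), Aldh1a1 (-2.67) and the VEGF receptor Flt1 (-3.23) were lower. The count of 2530 called genes was 918 and 887 without gallbladder organoid replicates 1 and 2, 1216 and 981 without liver organoid replicates 1 and 2, 7092 when only these 4 arrays were fitted, and 7399 with array weights. Centring each array on its median gave 29.7% higher against 48.7%.

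Against small intestine organoids, the question is how far gallbladder cultures differ from those of another endodermal epithelium. The intestinal program was lower in gallbladder organoids: the Paneth cell defensin Defa24 (-9.82 ± 0.29, adjusted p = 1.06e-08), sucrase-isomaltase (Sis, -8.28), Fabp1 (-7.80), lysozyme (Lyz1, -7.76), Adh1 (-7.56), Fabp2 (-7.22), Sult1d1 (-7.12) and Cyp3a11 (-7.09). Gallbladder organoids had more of the membrane mucin Muc1 (7.56 ± 0.40, adjusted p = 4.39e-07), the GABA receptor subunit Gabrp (7.46), the chemokine Cxcl5 (7.26), lactoferrin (Ltf, 7.22), ceruloplasmin (Cp, 7.11), lipocalin 2 (Lcn2, 6.66), Lbp (6.62) and Aspa (6.51). There were 4032 genes higher and 3068 lower, with a median over all genes of 0.11.

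Sox17 was higher in gallbladder than in small intestine organoids (3.58 ± 0.18) and averaged 9.98 there, 10.15 in differentiated and 10.43 in liver organoids and 6.40 in small intestine organoids, while Cdx2, the intestinal regulator, was lower (-3.72 ± 0.24), as was Gata4 (-3.90). All 23 enterocyte markers were lower (23 adjusted over the list alone, adjusted p = 2.45e-22), including alkaline phosphatase (Alpi, -6.68), and so were 11 of 15 intestinal stem cell genes (12 adjusted over the list alone, adjusted p = 2.17e-10), among them Smoc2 (-4.29), Aqp4 (-3.98), Ascl2 (-3.44), Axin2 (-2.56) and Lgr5 (-2.16). Both lists stayed called with an estimated correlation (0.0203 and 0.0174). Of 21 secretory cell markers 19 were lower and 1 higher (19 and 1 adjusted over the list alone, adjusted p = 3.22e-17), with Reg4 at -6.61 and Zg16 at -6.35, against an adjusted p = 0.058 with an estimated correlation. Cell cycle genes were lower too, 39 of 43 (39 lower and 1 higher adjusted over the list alone), with Mki67 at -2.44 and Nusap1 at -2.31 (adjusted p = 5.17e-22, and adjusted p = 0.0618 with an estimated correlation).

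YAP target and fetal-like genes were higher in gallbladder organoids, all 11 of them (11 adjusted over the list alone), led by Ankrd1 (5.13), Ccn2 (4.89) and Anxa3 (3.68), at adjusted p = 1.48e-08 and with an adjusted p = 0.0587 with an estimated correlation. Squamous genes were higher, 7 of 14 (8 adjusted over the list alone), with Ly6d at 6.26, Anxa8 at 5.31 and involucrin (Ivl) at 5.08 (adjusted p = 0.000118, and adjusted p = 0.173 with an estimated correlation). Bile duct markers were higher (adjusted p = 0.0432), with an adjusted p = 0.461 with an estimated correlation. Of these 15, 8 were higher and 2 lower (8 and 2 adjusted over the list alone), with Bicc1 at 5.31, Onecut1 at 3.65, and Aqp1 at -3.55. Tuft markers were lower, 6 of 12 (7 adjusted over the list alone), with Pou2f3, the tuft cell master regulator, at -1.81 (adjusted p = 0.00302, and adjusted p = 0.556 with an estimated correlation), and so were 4 of 13 nicotinamide and NAD genes (4 adjusted over the list alone) with Naprt at -2.10 (adjusted p = 0.0242, and adjusted p = 0.609 with an estimated correlation).

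Hepatocyte markers passed as lower (adjusted p = 0.00497), with an adjusted p = 0.859 with an estimated correlation. Their median was 0.02 and their mean -1.28, and 10 members were lower and 1 higher (10 and 1 adjusted over the list alone), the latter 2 without either gallbladder tissue array. The lower ones included Otc (-6.45), Cps1 (-6.18) and Apoa1 (-6.11), which enterocytes also express. Immediate early genes were higher, 6 of 14 (7 adjusted over the list alone) including Ier3 (3.21) and Hspa1a (2.83), at adjusted p = 0.0351 and with an adjusted p = 0.818 with an estimated correlation. That list was not called without small intestine tissue replicate 1 (0.0513) or 2 (0.0548), and had 11 higher members without either liver tissue array. Cd44 (2.71) and Prom1 (1.60) were higher, and Sox9 (0.35), Krt19 (0.27), Epcam (0.04) and Pdx1 (-0.92) did not pass. The 7100 called genes became 4533 without small intestine organoid replicate 2, 4580 without gallbladder organoid replicate 2, 11709 when only these 4 arrays were fitted, and 12112 with array weights. Centring arrays on their medians moved the median of all genes to -0.03 and the share higher from 56.8% to 39.9%.

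Gallbladder organoids were set against gallbladder tissue to ask what the culture keeps and what it lacks. Organoids had more of the chemokine Cxcl5 (6.88 ± 0.25, adjusted p = 4.66e-08), the cadherin Cdh17 (6.43), the lectins Reg3b (6.33) and Reg3g (5.78), Chil1 (5.69), the cornified envelope gene Sprr1a (5.63), the transporter Slc5a8 (5.52) and Anxa8 (5.52). Reg3b was at 8.05 without gallbladder tissue replicate 1 and 4.62 without replicate 2, and Reg3g at 7.55 and 4.01 in that order. Tissue had more of plasma protein and liver enzyme genes, Serpina1c (-8.71 ± 0.43, adjusted p = 3.42e-07), Alb (-7.83), Cyp3a11 (-7.66), Cyp4a12a (-7.53), Car3 (-7.41), Cyp2e1 (-7.37) and Ahsg (-7.37), and of the chloride exchanger Slc26a3 (-7.26). In all 6514 genes were higher in organoids and 3040 lower, with a median over all genes of 0.17.

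Every one of the 43 cell cycle genes was higher in the organoids (43 adjusted over the list alone), with Plk1 at 3.28, Ccna2 at 3.26 and Top2a at 3.13 (adjusted p = 3.02e-18, and adjusted p = 0.0751 with an estimated correlation). Lgr5 (3.16 ± 0.40), Sox9 (2.81), Mki67 (1.87), Cdx2 (1.46), Cd44 (1.06), Epcam (1.04) and Axin2 (0.47) were higher, and Krt19 (0.01), Sox17 (-0.46, adjusted p = 0.0613), Pdx1 (1.58, adjusted p = 0.088) and Lgr4 (-0.13) did not pass. Squamous genes were higher, 9 of 14 (9 adjusted over the list alone), with Ivl at 5.24 and Krt6a at 2.87 (adjusted p = 0.00142, and adjusted p = 0.241 with an estimated correlation).

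Stromal genes were lower in organoids. All 13 fibroblast markers were lower (13 adjusted over the list alone), with decorin (Dcn) at -7.23 and vimentin (Vim) at -5.78, and the list was called with both the preset (adjusted p = 5e-17) and an estimated correlation (0.0204). All 11 smooth muscle markers were lower (11 adjusted over the list alone), with Acta2 at -6.59 and desmin (Des) at -6.10 (adjusted p = 1.19e-16, and adjusted p = 0.0751 with an estimated correlation). Endothelial markers were lower in 12 of 13 (13 adjusted over the list alone), with Emcn at -4.88 (adjusted p = 3.9e-10, and adjusted p = 0.199 with an estimated correlation). Of 7 adipocyte markers 6 were lower (6 adjusted over the list alone), with Fabp4 at -4.20 (adjusted p = 0.000138, and adjusted p = 0.342 with an estimated correlation). Immune cell markers were lower, 10 of 19, and 1 was higher (10 and 1 adjusted over the list alone), with the class II antigen H2-Aa at -5.80 and Cd74 at -5.40 (adjusted p = 1.18e-06, and adjusted p = 0.461 with an estimated correlation). The number of immune markers higher was 0 without gallbladder organoid replicate 1 or 2 or gallbladder tissue replicate 2, and 2 without either small intestine tissue array. Interferon response genes were lower, 8 of 16 (8 adjusted over the list alone), and 5 without gallbladder organoid replicate 2, with Rtp4 at -2.37 (adjusted p = 0.000621, and adjusted p = 0.593 with an estimated correlation).

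Hepatocyte markers were lower in organoids than in gallbladder tissue in 29 of 30 (29 adjusted over the list alone, adjusted p = 8.02e-21, and adjusted p = 0.224 with an estimated correlation). Alb was at 14.3 on both gallbladder tissue arrays and in liver tissue, close to the highest signal of any gene on the gallbladder tissue arrays (14.72 and 14.75), where the scale no longer separates levels. Over 231 liver-restricted genes, the median signal of the gallbladder tissue arrays was the one that a share of liver RNA of 5.91% would give on replicate 1 and of 47.4% on replicate 2. Bile acid genes were lower, 10 of 16 (10 adjusted over the list alone), including the hepatocyte uptake carrier Slc10a1 (-6.09) and Cyp7a1, the rate-limiting enzyme of bile acid synthesis (-4.97, and -3.36 without gallbladder tissue replicate 2), at adjusted p = 0.000171 and with an adjusted p = 0.224 with an estimated correlation. Genes of the gallbladder epithelium were lower in 9 of 20 and higher in 2 (9 and 2 adjusted over the list alone, adjusted p = 0.0039, and adjusted p = 0.103 with an estimated correlation). Lower were Aqp1 (-4.65) and the cholecystokinin receptor Cckar (-4.33), and higher were Krt20 (4.45) and Mal (3.88). Without 660 genes at least 2 log2 units higher in liver tissue than in every organoid group, 9104 genes were called against 9554. The share higher was 79.9% with median centring against 68.2%, where the median of all genes was 0.34, and 0.28 with quantile normalisation.

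Liver organoids had more of bile duct genes than liver tissue and less of hepatocyte genes. All 30 hepatocyte markers were lower in the organoids (30 adjusted over the list alone, adjusted p = 1.39e-20, and adjusted p = 0.224 with an estimated correlation), with Serpina1c at -8.78, tryptophan dioxygenase (Tdo2) at -8.62, fibrinogen (Fgg) at -8.60, Pon1 at -8.46 and Alb at -8.15. Dmbt1 (7.60 ± 0.30, adjusted p = 5.31e-08), Gabrp (7.20), Adgrg7 (7.05) and Mmp7 (6.56) were the genes with the largest increase. Of 15 bile duct markers 11 were higher and 2 lower (11 and 2 adjusted over the list alone), with Krt19 at 6.41, Krt7 at 5.69 and Epcam at 5.32 (adjusted p = 0.000371, and adjusted p = 0.169 with an estimated correlation). The number lower was 0 without any array of liver tissue or of either kind of gallbladder organoid or without liver organoid replicate 2, and 1 without liver organoid replicate 1 or either small intestine organoid array. Sox17 (2.95), Sox9 (2.43), Cd44 (4.55) and Prom1 (4.13) were higher, and Lgr5 was at 0.26 (adjusted p = 0.655). A total of 5325 genes were higher and 3627 lower.

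Cell cycle genes were higher in liver organoids than in liver tissue, 38 of 43 with 1 lower (38 and 1 adjusted over the list alone), and 0 lower without liver organoid replicate 2, with Kif23 at 3.67 (adjusted p = 1.79e-12, and adjusted p = 0.121 with an estimated correlation). Tuft markers were higher, 7 of 12 (7 adjusted over the list alone), with Rgs13 at 4.75 and Gnat3 at 4.06 (adjusted p = 0.00843, and adjusted p = 0.607 with an estimated correlation). YAP targets were higher in 7 of 11 and lower in 1 (7 and 1 adjusted over the list alone, adjusted p = 0.00692, and adjusted p = 0.265 with an estimated correlation). Intestinal stem cell genes shifted up (adjusted p = 0.0253), with an adjusted p = 0.169 with an estimated correlation, as did hypoxia genes (adjusted p = 0.0197, and adjusted p = 0.607 with an estimated correlation), and nicotinamide and NAD genes shifted down with Nnmt at -6.46 (adjusted p = 0.03, and adjusted p = 0.633 with an estimated correlation). These 3 lists were not called without liver tissue replicate 2 (0.078, 0.0989 and 0.077). Immune (14 of 19), endothelial (12 of 13) and fibroblast markers (11 of 13) were lower, with 15, 12 and 12 adjusted over the list alone, and 1 endothelial marker was higher. C1qb was at -5.25, Eng at -4.51 and Dcn at -6.56. Their adjusted p-values were 2.07e-07, 4.27e-07 and 6.81e-08, and adjusted p = 0.415, 0.294 and 0.0751 with an estimated correlation.

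Small intestine organoids carried more stem and cell cycle transcripts than small intestine tissue. Of 15 intestinal stem cell genes 14 were higher (14 adjusted over the list alone), with Lgr5 at 3.79 ± 0.40 (adjusted p = 5.77e-05), Ascl2 at 2.71 and Aqp4 at 2.62, and the list was called with the preset (adjusted p = 1.19e-10) and an estimated correlation (0.0174). Of 43 cell cycle genes 42 were higher (42 adjusted over the list alone, adjusted p = 1.13e-22, and adjusted p = 0.0587 with an estimated correlation). Wnt targets were higher in 10 of 16 and lower in 3 (10 and 3 adjusted over the list alone), and 1 was lower without small intestine organoid replicate 2 (adjusted p = 0.00243, and adjusted p = 0.0837 with an estimated correlation). Ak4 (4.64), Cyp2c38 (4.36) and C4bp (3.87) were higher, Cyp2c38 by 2.70 without small intestine tissue replicate 1, and Slc5a12 (-7.46), cubilin (Cubn, -7.23), H2-Aa (-6.80) and Pmp22 (-6.43) lower. In total 4027 genes were higher and 3102 lower.

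Enterocyte markers were lower in small intestine organoids than in their tissue, 14 of 23 (15 adjusted over the list alone), with lactase (Lct) at -5.24 and Slc6a19 at -2.72 (adjusted p = 3.08e-06, and adjusted p = 0.121 with an estimated correlation). BMP targets were lower, 5 of 11 (5 adjusted over the list alone), with Smad7 at -2.45 and Id3 at -1.59 (adjusted p = 0.0318, and adjusted p = 0.183 with an estimated correlation). That call ended without small intestine tissue replicate 2 (0.0521), and 3 members were lower without that array or either organoid array. Fibroblast markers were lower in all 13 (13 adjusted over the list alone) by either correlation (adjusted p = 4.36e-11 and 0.0451), as were 18 of 19 immune markers (18 adjusted over the list alone, adjusted p = 3.38e-13, and adjusted p = 0.224 with an estimated correlation). Interferon response genes were lower, 11 of 16 (12 adjusted over the list alone), with Oasl2 at -4.01 (adjusted p = 3.66e-06, and adjusted p = 0.416 with an estimated correlation). Tissue replicate 2 was above replicate 1 in 16 of 16 interferon response genes (median 1.14) and 18 of 19 immune markers (median 0.93), and the interferon list had an adjusted p of 1.22e-09 without replicate 1 and 0.000147 without replicate 2. limma called 0 of 10 pancreatic acinar markers, 5 were lower at an unadjusted p under 0.05, and 10 were lower without small intestine tissue replicate 1 and 3 higher without replicate 2, the array on which the acinar list was higher by a median of 5.91. Median centring gave 69.7% higher against 56.5%, with a median over all genes of 0.13.

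**Figure D2:**
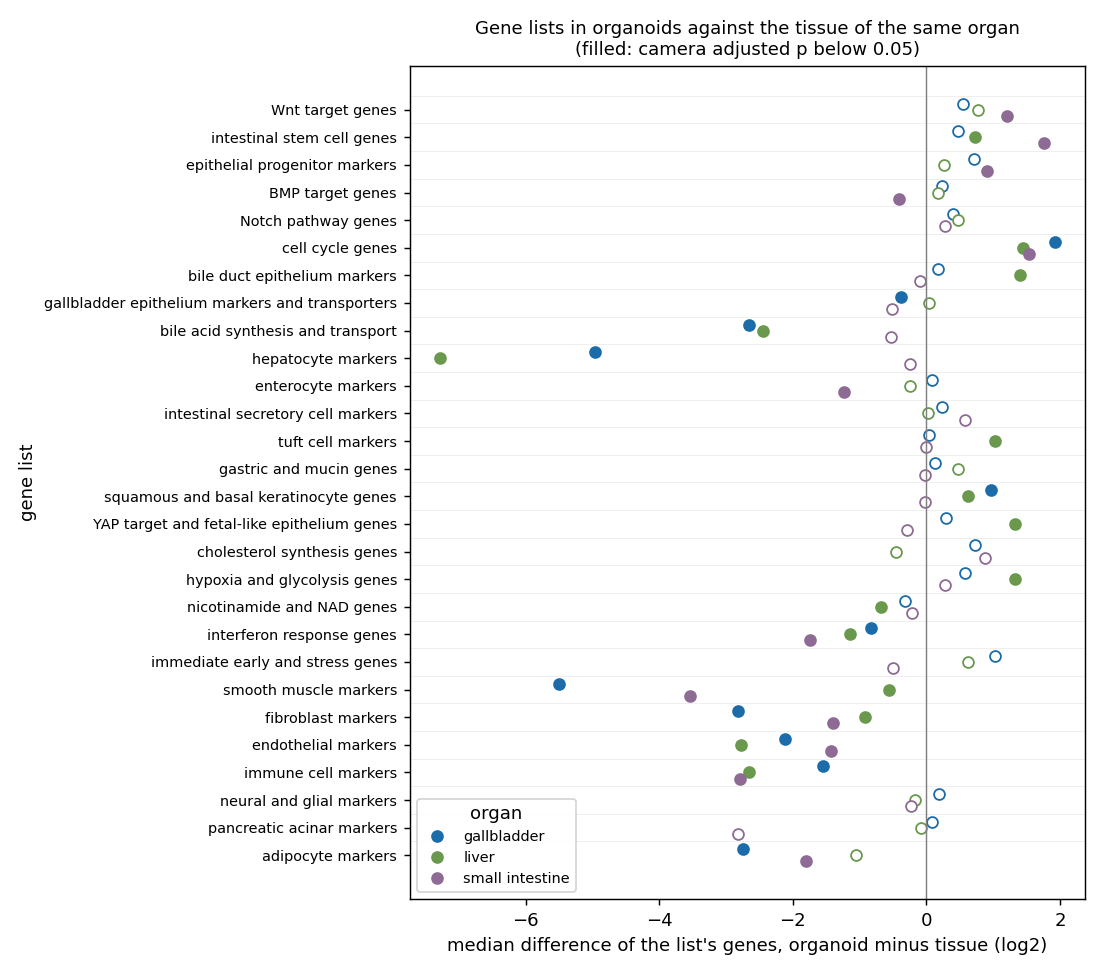
Median log2 difference between organoids and tissue of each of 28 gene lists, for gallbladder, liver and small intestine (filled points are lists with a camera adjusted p below 0.05, open points are not). Cell cycle genes are higher in the organoids of all 3 organs, and fibroblast, endothelial, smooth muscle and immune cell markers are lower.

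Changes common to the 3 organoid-tissue comparisons, which share no array, numbered 1355 higher and 599 lower genes. Independent lists would give 351.4 and 86.0. The lists are not independent, since all 3 use the same variance estimate of a gene, which by itself raises the overlap. Cell cycle genes made up 38 of the former, out of 43. Fibroblast markers (11 of 13), immune cell markers (9 of 19), endothelial markers (8 of 13) and smooth muscle markers (6 of 11) were lower in all 3. The integrin Itga2 (mean difference 4.08), Tnip3 (3.68), the serine synthesis enzyme Psat1 (3.63) and Il1rn (3.31) were highest, and Dcn (-6.62), Car3 (-6.55), H2-Aa (-5.89) and Serpina3n (-5.58) lowest. Another 862 genes were called in all 3 but in differing directions.

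Gallbladder and liver tissue differed in epithelium, muscle and liver enzymes. Dmbt1 (8.11 ± 0.30, adjusted p = 9.29e-08), the intestinal-type mucin Muc3 (7.95), Adgrg7 (7.51) and Slc9a3 (7.25) were higher in gallbladder, and Cyp3a16 (-7.44 ± 0.25, adjusted p = 5.54e-08), Sult3a1 (-7.03), A1bg (-6.44) and Cyp2a22 (-5.58) were lower. Cyp3a16, Sult3a1 and A1bg are female-biased liver genes and were low on both gallbladder arrays. Gallbladder tissue replicate 2 had little Xist (5.46, against 11.94 and 12.27 in liver tissue). Of 15 bile duct markers 12 were higher and 1 lower (12 and 1 adjusted over the list alone), led by Krt19 (6.03) and Krt7 (3.39) (adjusted p = 4.21e-07, and adjusted p = 0.0751 with an estimated correlation). Sox17 (2.95), Muc1 (6.70) and Cckar (4.29) were higher, and Alb, near the top of the scale in both tissues, gave no usable difference (-0.05, adjusted p = 0.94). All 11 smooth muscle markers (11 adjusted over the list alone) and 12 of 13 fibroblast markers (12 adjusted over the list alone) were higher, with Actg2 at 5.75 and Vim at 2.64. Their adjusted p-values were 4.34e-13 and 2.31e-09, and adjusted p = 0.106 and 0.0587 with an estimated correlation.

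Hepatocyte markers were lower in gallbladder than in liver tissue in 18 of 30 (20 adjusted over the list alone), with Asgr1 at -3.55 and Arg1 at -2.90 (adjusted p = 0.000494, and adjusted p = 0.763 with an estimated correlation). This number was 9 and 10 without liver tissue replicates 1 and 2 and 11 without gallbladder tissue replicate 1, where Asgr1 was at -1.96 and Arg1 at -1.88. Cholesterol synthesis genes were lower, 12 of 15 (12 adjusted over the list alone), 7 without liver tissue replicate 1 and 6 without gallbladder tissue replicate 1, with Lss at -2.17, or -1.38 without the latter (adjusted p = 0.00407, and adjusted p = 0.692 with an estimated correlation). In all 4125 genes were higher and 5472 lower, and 3824 were called when only these 4 arrays were fitted (57.8% higher against 43%), 5910 with array weights. The common variance includes the organoid arrays, whose replicates varied less (pooled SD 0.0952 to 0.136 against 0.289 to 0.404 in tissues). Calls between tissues can therefore be too many and their adjusted p-values too low, though the fit to 4 arrays also has fewer degrees of freedom. The share higher was 30.7% with quantile normalisation (median of all genes -0.27) and 25.1% with median centring (-0.31).

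Gallbladder tissue had less of the intestinal program than small intestine tissue: Defa24 (-9.35 ± 0.29, adjusted p = 1.01e-08), Sis (-8.67), Clca4b (-8.38), Zg16 (-8.07), Cdx2 (-4.75) and Gata4 (-2.13) were lower. It had more Cyp4a12a (7.64), its relative Cyp4a12b, Tdo2 (7.16), Muc1 (6.94), Alb (5.32) and Sox17 (3.31). Tdo2 was at 8.28 without gallbladder tissue replicate 1 and 6.04 without replicate 2. Enterocyte markers were lower in 21 of 23 (21 adjusted over the list alone) by either correlation (adjusted p = 9.21e-17 and 0.0334). Secretory cell markers were lower in 18 of 21 and higher in 1 (18 and 1 adjusted over the list alone, adjusted p = 6.19e-11, and adjusted p = 0.0962 with an estimated correlation), and cell cycle genes in 41 of 43 (42 adjusted over the list alone, adjusted p = 1.27e-18, and adjusted p = 0.0751 with an estimated correlation). YAP targets were higher in 10 of 11 and lower in 1 (10 and 1 adjusted over the list alone), with Clu at 3.70 (adjusted p = 4.08e-05, and adjusted p = 0.117 with an estimated correlation). Smooth muscle markers were higher in 11 of 11 (11 adjusted over the list alone), with Tagln at 2.45 (adjusted p = 9.25e-08, and adjusted p = 0.215 with an estimated correlation).

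Hepatocyte markers were higher in gallbladder than in small intestine tissue in 22 of 30 and lower in 3 (22 and 3 adjusted over the list alone, adjusted p = 3.02e-08, and adjusted p = 0.556 with an estimated correlation), and 1 was lower without small intestine tissue replicate 1. Immune cell markers were lower, 10 of 19 (10 adjusted over the list alone), with the B cell gene Ms4a1 at -2.98 (adjusted p = 0.00302, and adjusted p = 0.692 with an estimated correlation), and an adjusted p of 0.0784 without small intestine tissue replicate 2. A total of 4135 genes were higher and 4838 lower, and 3224 were called when only these 4 arrays were fitted, 5154 with array weights. As between gallbladder and liver tissue, the common variance includes the less variable organoid arrays, so calls can be too many. The share higher was 46.1%, and 34.6% with quantile normalisation (median of all genes -0.19) and 30.3% with median centring (-0.20).

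Liver organoids also had less of the intestinal program than small intestine organoids. Gabrp (7.57 ± 0.18, adjusted p = 4.7e-09), Muc1 (7.27), Ltf (6.58), Efemp1 (6.29) and Sox17 (4.04) were higher, and Defa24 (-9.43), Sis (-8.47), Fabp1 (-7.44), Fabp2 (-7.33), Cdx2 (-3.99) and Lgr5 (-3.37) lower. Among the lists, 5 were called by either correlation. Enterocyte markers were lower in 22 of 23 (22 adjusted over the list alone, adjusted p = 1.43e-22 and 0.0203), and cell cycle genes in 41 of 43 (42 adjusted over the list alone, 3.45e-30 and 0.0451). Stem cell genes were lower in 13 of 15 and higher in 1 (13 and 1 adjusted over the list alone, 2.78e-12 and 0.0174), and secretory cell markers in 19 of 21 with 1 higher (19 and 1 adjusted over the list alone, 3.27e-19 and 0.0451). The stem cell gene that was higher was not called without any single organoid array. YAP targets were higher in 10 of 11 (11 adjusted over the list alone, 2.17e-10 and 0.0451), with Ccn2 at 5.43. BMP targets were higher in 6 of 11 and lower in 1, or in 0 without any 1 of the 4 arrays compared (6 and 1 adjusted over the list alone), with Id1 at 2.44 and Smad7 at 2.32 (adjusted p = 0.0039, and adjusted p = 0.103 with an estimated correlation). There were 2835 genes higher and 2440 lower, and 8191 called with array weights.

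Differentiated gallbladder organoids were compared with gallbladder tissue to see how near withdrawal of the factors brings the culture to the organ. Lgr5 was at 0.01 (adjusted p = 0.988), or at -0.67 without gallbladder tissue replicate 1 and 0.69 without replicate 2, as the tissue arrays read 6.54 and 7.90. Liver tissue read 9.40 and 8.41, and replicate 2 had the larger estimated liver share (47.4%). The gallbladder's own level of Lgr5 is therefore uncertain. Axin2 was at -0.15 (adjusted p = 0.277). Undifferentiated organoids were above tissue by 3.16 (Lgr5) and 0.47 (Axin2), and the cultures themselves differed by -3.15 and -0.62. Tuft markers were above the tissue in 8 of 12 (9 adjusted over the list alone), with Gnat3 at 3.84 and Rgs13 at 2.99 (adjusted p = 0.00243, and adjusted p = 0.55 with an estimated correlation). Cell cycle genes were above tissue in 43 of 43 (43 adjusted over the list alone), with Plk1 at 3.70 and Mki67 at 2.51 (adjusted p = 3.04e-21, and adjusted p = 0.065 with an estimated correlation). The genes furthest above tissue were Cdh17 (6.89 ± 0.13, adjusted p = 4.98e-09), Sprr1a (6.16), Cxcl5 (6.04) and Il1a (5.74), and those furthest below were Serpina1c (-8.84), Alb (-7.71), Cyp3a11 (-7.62) and Cyp2e1 (-7.51).

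All 13 fibroblast markers were below the tissue level in differentiated organoids (13 adjusted over the list alone) by either correlation (adjusted p = 7.59e-18 and 0.0203). Gallbladder epithelium genes were lower in 8 of 20 and higher in 2 (8 and 2 adjusted over the list alone), with Cckar at -4.33 and Krt20 at 5.21 (adjusted p = 0.0172, and adjusted p = 0.146 with an estimated correlation). Squamous genes were higher in 9 of 14 (9 adjusted over the list alone), with Ivl at 5.19 and Dsg3 at 3.51 (adjusted p = 9.01e-05, and adjusted p = 0.169 with an estimated correlation). There were 5710 genes higher and 2808 lower, against 6514 and 3040 for undifferentiated organoids. The total of 8518 was 5659 without differentiated organoid replicate 1, and the share higher was 80.9% with median centring (median of all genes 0.32) and 67% without, where the median was 0.12, and 0.23 with quantile normalisation.

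Genes that mark 1 tissue among the 3 were followed into the organoids, to ask whether cultures keep the identity of their organ. Of 393 genes of the small intestine signature, 283 (72.0%) were higher in small intestine organoids than in both other origins and 19 were lower, against 15.7% of all genes being higher (Fisher's exact test, p = 5.39e-141), with Defa24, Sis, Reg4 and Alpi the most specific. The 283 included 15 enterocyte markers, 13 secretory cell markers and 13 cell cycle genes, so they do not all mark organ identity. Of 201 gallbladder signature genes, 40 (19.9%) were higher in gallbladder organoids and 5 lower, against 13.3% of all genes (Fisher's exact test, p = 0.00882), led by the protocadherin Pcdh11x, the non-coding RNA Meg3, Lix1l and the DNA sensor Aim2. Of 180 liver signature genes, 17 (9.44%) were higher in liver organoids and 11 lower, against 7.80% (Fisher's exact test, p = 0.401), led by Fabp7, Clec12a, Atp6v0d2 and the glycine cleavage enzyme Gldc. Fisher's exact test treats genes as independent, so these p-values do not measure the spread between replicates or allow for genes that move together. The liver signature held 1 of 30 hepatocyte markers. A signature gene had to be called and 2 log2 units above each other tissue, and Alb, for one, was near the top of the scale in gallbladder tissue too. The minimum alone does not explain the rest, as Asgr1 (-3.55), Arg1 (-2.90) and F2 (-2.54) passed it in gallbladder against liver tissue. Which requirement left out each marker was not tested. The number of gallbladder genes was 25 without gallbladder organoid replicate 2 or gallbladder tissue replicate 1. For liver it was 11 without gallbladder organoid replicate 2, 5 and 11 without liver tissue replicates 1 and 2, 10 without gallbladder tissue replicate 1, and 49 of 473 without gallbladder tissue replicate 2.

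The gallbladder signature rose as a set when the factors were withdrawn, with 29 genes higher and 8 lower in differentiated than in undifferentiated organoids (camera, adjusted p = 1.51e-07, and p = 0.228 with an estimated correlation). Its median was 0.15. The small intestine signature was called up as well, on a minority of its genes, with 43 higher and 17 lower of 393 and a median of 0.01 (camera, adjusted p = 0.00175, and p = 0.087 with an estimated correlation). The liver signature did not pass, with 5 higher and 3 lower (camera, adjusted p = 0.836). Between gallbladder and small intestine organoids 130 genes of the gallbladder signature were higher and 5 lower (camera, p = 2.36e-19, and p = 0.0655 with an estimated correlation). Between gallbladder and liver organoids 17 genes of the gallbladder signature were higher and 29 lower, and it did not pass (camera, p = 0.132, and p = 0.726 with an estimated correlation). These counts come from the fit to all arrays, where calls between organoids can be too few. The 40 signature genes higher in gallbladder organoids than in both other origins came from the separate fit to undifferentiated organoids. The numbers therefore cannot be compared directly. In the fit to all arrays, gallbladder organoids exceeded small intestine organoids in the signature with the preset correlation only. They were not shown to exceed liver organoids. Across the 10 comparisons, 105 of 280 list tests were called with the preset correlation, and 12 of these with an estimated one, while fry called 96 of them. The estimated correlation gave the highest adjusted p of all alternatives for 103 of the 105, and leaving out the dimmest 40% of genes gave it for the other 2.

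Leaving out those dim genes ended 22 of the list calls and fry did not make 9. After factor withdrawal, cell cycle genes had 0.0845 without dim genes and 0.228 by fry, bile duct markers 0.0754 without dim genes, and hypoxia genes 0.0909 by fry. Between gallbladder and liver organoids, hypoxia genes had 0.0523 and 0.084 in that order of settings, and interferon genes 0.0934 and 0.261. Between gallbladder and small intestine organoids, bile duct markers (0.061) and nicotinamide and NAD genes (0.0959) were not called without dim genes, nor hepatocyte markers by fry (0.112). In liver organoids against their tissue, leaving out dim genes ended the calls of stem cell genes (0.177), hypoxia genes (0.16), YAP targets (0.0754) and tuft markers (0.0542). Between gallbladder and small intestine tissue it ended the call of immune markers (0.103).

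**Figure D3:**
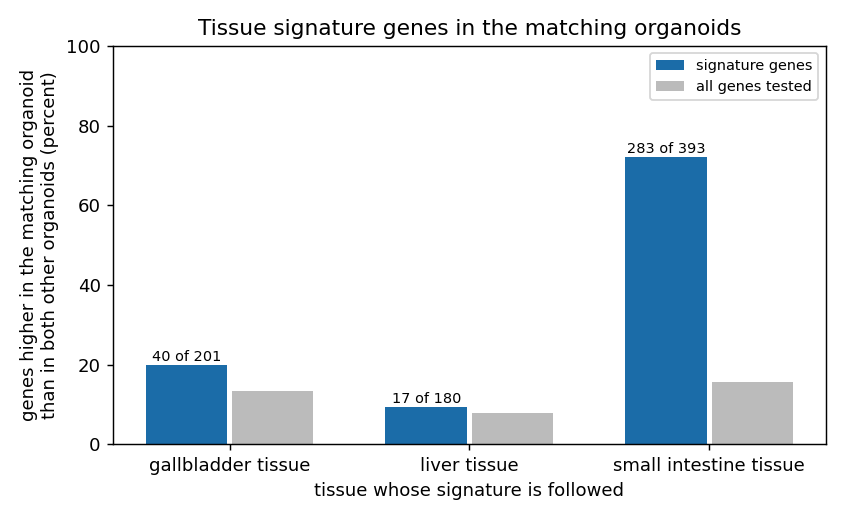
Percent of the genes of each tissue signature (40 of 201 for gallbladder, 17 of 180 for liver, 283 of 393 for small intestine) that were higher in the matching organoids than in the organoids of both other origins, beside the same percent over all 19938 genes. The small intestine signature stands at 72.0% against 15.7%.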

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

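The interaction tests were planned, and the tests of explanations for the 3 patterns that follow them were chosen after the results had been seen.

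The organoid-tissue difference of gallbladder differed from that of liver for 7929 genes, and from that of small intestine for 7297 genes, by an interaction test in limma (adjusted p below 0.05), a difference between groups. Against liver, 4523 genes had the more positive difference in gallbladder and 3406 the more negative one. The most positive were Cyp3a16 (7.37), Sult3a1 (6.95), A1bg (6.59) and Trf (6.34, not exact, as its signal in liver tissue was near the top of the scale), and the most negative Cyp4a12a (-10.17), the glycosyltransferase B4galnt2 (-9.49), Muc3 (-8.40) and Cyp4a12b (-8.38). Cyp3a16, Sult3a1 and A1bg averaged 11.75, 11.34 and 12.14 in liver tissue and 4.18, 3.69 and 5.66 over the organoids and small intestine tissue. Their interactions thus follow mainly from the level in liver tissue, not from a difference between organoids. These genes are female-biased in liver, and Cyp4a12a and Cyp4a12b male-biased. Of the 7929 genes, 1035 were called in both organs in opposite directions and 1568 in the same direction. Against small intestine, 4450 were more positive and 2847 more negative. Slc5a8 (8.80), Ly6m (8.45), Slc5a12 (7.44) and Krt20 (7.38) stood at one end, and Cyp2c29 (-10.23), Cyp2c70 (-8.89), Cyp2c38 (-8.63) and Ces1c (-7.77) at the other, and 940 genes were called in opposite directions. Without small intestine tissue replicate 1 Slc5a8 was at 5.67 and Cyp2c29 at -7.48, and without replicate 2 at 11.93 and -12.98, and Cyp2c38 was at -6.97 and -10.29 in that order. Without gallbladder tissue replicates 1 and 2 Cyp2c29 was at -11.69 and -8.77 and Cyp2c70 at -10.51 and -7.27. Without the genes higher in liver tissue, an alternative chosen after seeing the data, the counts were 7633 and 7106.

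Transcripts of hepatocytes were abundant on both gallbladder tissue arrays, with Alb at 14.3, and 222 of 231 liver-restricted genes were higher on replicate 2 than on replicate 1, by a median of 2.42. Liver tissue in the gallbladder RNA is a candidate source. On the array where it held least well, 91.8% of the liver-restricted genes lay no more than 2 log2 units below the level that a liver share of 5.91% (replicate 1) or 47.4% (replicate 2) gives. Each share was the median over these same genes and only the lower side was bounded. A high percent was thus largely built in and does not decide for liver tissue. The exceptions, 7 genes on replicate 1 and 19 on replicate 2, included Cyp3a16, Sult3a1 and A1bg on both, and 15 and 2 genes lay over 2 log2 units above that level. Female livers express these 3 genes more, yet they were low on replicate 1 with its Xist signal. Other female-biased genes went the other way: Cyp2b9 was at 11.35 on replicate 1 and 6.17 on replicate 2, and Cyp2b13 at 7.48 and 4.97. On replicate 1 Cyp4a12a was at 12.57 against 5.73 and 5.74 in liver tissue. A liver like the one measured does not give the values of Cyp4a12a, Cyp3a16, Sult3a1 and A1bg. The female-biased genes as a set do not decide, as they differ among themselves. Expression by gallbladder cells cannot be told apart from liver tissue in the RNA, since 34 epithelial markers differed by a median of -0.29 between the replicates, where dilution by liver would give -0.84.

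The genes that set gallbladder organoids apart from differentiated and from liver organoids overlapped, with 544 of the 943 and 2530 called genes called in both in the same direction (304 lower and 240 higher in gallbladder organoids) and 17 in opposite directions. Both comparisons use the same 2 gallbladder organoid arrays, but chance spread between those 2 arrays is argued against as the source. The covariance of the 2 differences across genes was 0.109, which is 22.6 times the replicate variance of the mean of those arrays (0.00485). The highest of 20 simulations without a difference was 0.00752. The correlation (0.577 against at most 0.537) and the share of genes with the same sign (70.8% against at most 67.3%) were only a little higher than simulated. Sharing arrays raises both by itself. The variance and the simulations rest on the spread between replicates, which may be technical. A chance trait of a culture or batch that both arrays share is therefore not excluded. A state of the gallbladder organoid cultures that no other organoid group has may be the source, but its test decided nothing: 67.1% of the shared genes also differed the same way from small intestine organoids and 79 the opposite way, on the same gallbladder organoid arrays and with 35.6% of all genes called there. From gallbladder tissue 67.7% differed the same way and 71 genes the opposite way, with 47.9% of all genes called. Such a state cannot be told apart from features that differentiated and liver organoids have in common, because only 1 set of undifferentiated gallbladder cultures was measured. The shared genes include the tuft markers Rgs13 and Gnat3, so this limit also holds for their rise after withdrawal.

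One gallbladder tissue array, replicate 2, carried Y-linked transcripts and little Xist. Eif2s3y was at 10.0, Kdm5d at 8.49 and Uty at 9.80, against at most 5.40 for any of these genes on the other 13 arrays. RNA of both sexes pooled on that array is argued against, since Xist lay 6.11 log2 units below the lowest other array. A male animal is a candidate explanation: on that array the difference to liver tissue was higher by 9.47 log2 units for male-biased than for female-biased liver genes, against 1.91 on replicate 1. Of the male-biased genes 9 of 9 lay above liver tissue, against 2 on replicate 1, while 0 of 7 female-biased genes did on either array. Those 2 were Cyp4a12a (12.57, and 13.17 on replicate 2) and Cyp4a12b (11.46 and 12.78), high on both arrays. Replicate 1 had the smaller estimated liver share (5.91% against 47.4%). The contrast between the replicates therefore also reflects liver content and does not measure sex alone. Sex and replicate are confounded within gallbladder tissue, so the part of the replicate difference that sex gives stays open.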

How the results depend on the processing

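All settings were planned except those that leave out liver-enriched genes or acinar markers, choose the gallbladder signature without gallbladder tissue replicate 2, or cross the block, which were chosen after seeing the data. All 12 counts of called genes stayed within 1.5 times their value with quantile normalisation, median centring, dim genes left out, averaged probe sets, a trended prior and the replicate block. With the block, 105 of 105 list calls stayed, and differentiated against undifferentiated gallbladder organoids gave 888 genes, or 884 with its numbers crossed. Of 15686 alternative values of named genes, 15271 kept their side of the threshold, 256 lost and 159 gained a call, and the sign changed in 33, 0 of them of a gene called at first. Where an array is left out, the lone array is assumed to vary like the other groups. Signals near background compress differences, and no detection call was given.

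Fitting only the arrays of the groups compared drops the spread of the other groups. For organoids this leaves out the more variable tissues and gave 5353 genes for differentiated against undifferentiated gallbladder organoids, 7092 for gallbladder against liver organoids and 11709 against small intestine organoids. Calls between organoids in the main fit can therefore be too few. For tissues it leaves out the less variable organoids and gave 3824 for gallbladder against liver tissue and 3224 against small intestine tissue. Array weights gave 5720, 7399, 12112, 5910 and 5154 in that order, and 8191 for liver against small intestine organoids; the cause was not tested. A minimum of 1 log2 unit, which removes genes by construction, gave 427, 746, 2694, 3658, 3516 and 2479 in that order of 6. It gave 3234, 4447 and 2884 for gallbladder, liver and small intestine organoids against their tissues, 3022 for differentiated organoids against gallbladder tissue, 4071 and 3470 for the interactions with liver and small intestine, and 532 genes shared by the 3 organoid-tissue comparisons.

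For lists after factor withdrawal, an estimated correlation gave adjusted p-values of 0.204 (stem cell), 0.607 (cell cycle), 0.339 (bile duct), 0.121 (tuft) and 0.522 (hypoxia), and fry 0.0021 (Wnt), 0.228 (cell cycle) and 0.0909 (hypoxia). With fewer genes, dim ones left out, cell cycle had 0.0845 and bile duct 0.0754. Over all settings the adjusted p was 0.0021 to 0.305 (Wnt), 0.00168 to 0.204 (stem cell), 0.00125 to 0.607 (cell cycle), 0.0059 to 0.339 (bile duct), 2.21e-15 to 0.121 (tuft) and 0.000809 to 0.522 (hypoxia). Tissue signatures of at least 1 log2 unit gave 144 of 751 (gallbladder), 46 of 507 (liver) and 571 of 922 (small intestine) genes higher in the matching organoids, and of at least 3 gave 11 of 48, 3 of 54 and 167 of 197, as more or fewer genes enter. Direction alone gave 101 and 44 for the gallbladder and liver signatures.

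Leaving out single arrays gave 338 to 1390 genes (differentiated against undifferentiated), 887 to 3494 (gallbladder against liver organoids), 4533 to 8167 (against small intestine organoids), 3565 to 5934 (liver against small intestine organoids), 6613 to 10299 (gallbladder organoids against tissue), 7012 to 9472 (liver), 5047 to 8007 (small intestine) and 5659 to 9277 (differentiated organoids against gallbladder tissue). It gave 7635 to 10309 and 7938 to 9387 for gallbladder against liver and small intestine tissue, 5704 to 9064 and 4932 to 7913 for the interactions, and 1498 to 2266 for the shared set. Adjusted p ranged over 0.0775 to 0.165 (Wnt), 0.0276 to 0.0805 (stem cell), 0.00125 to 0.0812 (cell cycle), 0.0059 to 0.0271 (bile duct), 2.21e-15 to 1.61e-10 (tuft) and 0.000809 to 0.0201 (hypoxia), and signature genes over 25 to 53, 5 to 49 and 255 to 311. The pairing of replicate numbers left little trace: over 21 pairs of groups the correlation of replicate differences was -0.104 to 0.139, with a median of -0.0031.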

Other observations

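No test of an explanation was chosen for the values given here, which were picked after the arrays had been seen.

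Replicates within a tissue differed in whole gene groups. Pancreatic acinar markers were higher on small intestine tissue replicate 2 than on replicate 1 in 10 of 10 genes, by a median of 5.91 log2 units. Immune cell markers were higher on the same array in 18 of 19 genes (median 0.93), and interferon response genes in 16 of 16 (median 1.14). The sodium-coupled transporter Slc5a8, which colon and distal intestine express, was at 13.26 on one small intestine tissue array and 6.99 on the other. Cholesterol synthesis genes were higher on gallbladder tissue replicate 2 than on replicate 1 in 15 of 15 genes, by a median of 1.55.

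Sox17 averaged 10.44 in gallbladder tissue and 9.98 and 10.15 in the undifferentiated and differentiated gallbladder organoids, 10.43 in liver organoids, 7.49 in liver tissue, 6.40 in small intestine organoids and 7.14 in small intestine tissue. Cdx2 averaged 12.36 in small intestine organoids and 11.94 in small intestine tissue. Lgr5 averaged 12.54 in small intestine organoids, 10.37 in gallbladder organoids, 9.16 in liver organoids and 7.23 in differentiated gallbladder organoids, against 8.75, 7.22 and 8.90 in small intestine, gallbladder and liver tissue.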
